A study of Mus musculus with 36 samples.

How the data were processed

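Eosinophils, granulocytes of blood and mucosal tissues, were flow-sorted from C57BL/6 mice aged 8 to 12 weeks at steady state, with males and females pooled, per the labels. Total eosinophils came from 7 tissues in 24 libraries: bone marrow (3), blood (4), spleen (4), lung (3), skin (3), colon (3) and small intestine (4). A separate set of 11 libraries held small intestine eosinophils from mice in which the fluorescent protein TdT reports Nmur1, the receptor of the neuropeptide neuromedin U, with 5 libraries of reporter-positive and 6 of reporter-negative cells. A further single-cell sample was not analysed here. Libraries were made with Smart-seq2, a full-length cDNA method, and read as 150 bp pairs, per the labels. Groups and replicate numbers came from the sample titles. The labels do not say that replicates were separate animals, so p-values measure the spread between these libraries, which may be partly technical.

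The authors deposited 2 tables of normalised transcript abundance (TPM), each with 1 column per library, for 9844 genes in the tissue libraries and 8001 genes in the sorted libraries, with 7941 genes in both. TPM divides the reads of a gene by its transcript length and scales each library to a fixed total, so the deposited TPM values keep no sequencing depth, and the depth of each library is unknown. Per the submitters' processing notes, cutadapt 2.10, STAR 2.7.5c and RSEM 1.3.3 were used with the mouse build mm10. The annotation, the read totals and the rule by which genes were removed before deposit are not given in the sources used here. Every deposited gene was above 0 in at least 3 tissue libraries or at least 6 sorted libraries. A gene found only in the 5 positive libraries could therefore not be in the sorted table. A gene found only in the 6 negative libraries could be. Because genes had been removed, deposited TPM columns summed to between 796048 and 890768 in the tissue table and between 799585 and 863816 in the sorted table. Mitochondrially encoded genes, a list of 0 measured members in both tables, were therefore not analysed here. No per-sample column was left unused. The tables were analysed separately, and no level was compared across them.

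Values were analysed as log2(TPM + 1) with limma 3.58.1 in R 4.3.3. Genes with a TPM of at least 1 in at least 3 libraries of the tissue table (9806 genes) or at least 5 libraries of the sorted table (7982 genes) were tested. A linear model with tissue or sort as the only term was fitted with lmFit and eBayes (trend, not robust), two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. All 24 tissue libraries shared 1 estimate of the spread. Small intestine was compared with the unweighted mean of the 6 other tissue means, with each of the 6, and with every other tissue at once. The last took, per gene, the largest of the 6 pairwise p-values where all 6 changes had the same sign. Reporter-positive libraries were compared with reporter-negative libraries. A change on the log2(TPM + 1) scale understates the change of low genes. The median change of all genes was 0.111 for small intestine against the mean of 6 tissues and 0.216 for positive against negative libraries, and median-ratio scaling moved these medians to 0.011 and 0.045. Changes of genes and lists are therefore given relative to the median gene of the comparison. Exceptions are Nmur1 itself, the test against every other tissue, and values under other settings. Gene calls and limma p-values test the change against 0 before this shift. In the sort the 0.216 thus counts towards a higher call and against a lower one.

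The comparisons, tests, alternatives, the rule for naming genes and 44 gene lists were fixed before the data were examined. Lists of at least 3 measured members were tested with camera of limma, with a preset correlation of 0.01 between genes and, as an alternative, an estimated one, with Benjamini-Hochberg adjustment over lists. Unless an estimated correlation is named, an adjusted p of a list is from the preset one. Members were counted with adjustment over all genes tested and adjusted over the list alone. The rule named the 10 largest rises and 10 largest falls of each main comparison, 5 of each for the others, up to 4 called members of each list with the largest change (the 2 most abundant where none was called), and Nmur1. Largest changes needed an adjusted p under 0.05, a mean of at least 10 TPM in the higher group, a named gene model outside the ribosomal protein genes, and every library of the small intestine or positive group on the same side of the other mean. The text names part of the genes this rule gives, and that part was chosen after the values and their stability had been seen. A few genes the rule gives are not reported here, and the others are all counted under the alternatives. Nmur1 was also tested with exact two-sided permutation tests of the mean log2(TPM + 1).

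Coordinates, transcript lengths and GC content came from the GENCODE mouse annotation of the same build, matched by symbol, with 9802 of 9904 symbols found and 9789 with a length. It may differ from the annotation the authors used. Genes of near-identical families (Ear1 and Ear2, Defa17, Lyz1 and Lyz2, H2-Q6, Klra17, Sirpb1a, Hba-a1, Hbb-bt, ribosomal protein genes with their pseudogenes) can share reads, and their values are uncertain to that extent.

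Replicate numbers 3, 4, 5 and 8 occur in both sorts. Deviations from the group means correlated by 0.16 to 0.23 across genes in the 4 same-numbered pairs. Of the 4 positive libraries 3 matched their own number best. Positive replicate 8 matched negative replicate 7 (0.19) better than negative replicate 8 (0.16). Some other differently numbered pairs also exceeded 0.1, such as positive 3 with negative 5 (0.14). The numbers were taken to pair these libraries. The main fit stayed unpaired, as fixed before the data were examined. This pairing comes from the titles and that check. The fit with the replicate number as a block is given beside a result where it changes the call. Correlations of log2 values between libraries ranged from 0.919 to 0.973 within tissues and from 0.917 to 0.947 within sorts, and no 2 columns were identical.

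The alternatives were pseudocounts of 0.1 and 5, no filter or a minimum of 5 TPM, median-ratio scaling, quantile normalization, library weights, robust eBayes, a change of at least 2-fold, ribosomal protein genes left out, only the 2 tissues compared in the fit, the replicate block, and leaving out each library in turn. Added after seeing the data were lung, skin and colon alone as the other side, haemoglobin genes left out, and the block with median-ratio scaling.

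The code was tested on simulated data drawn from the real gene means and residual spread, with 200 genes changed. Of 100 genes changed 2-fold and 100 changed 4-fold, 70 and 96 were recovered for small intestine against the mean of 6 tissues (9698 genes), 15 and 68 against every other tissue (9698 genes), and 52 and 96 for positive against negative (7971 genes). In these runs 9, 0 and 7 unchanged genes were called. Figures were drawn with matplotlib 3.10.9.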

Results

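The series measured gene expression in eosinophils sorted from 7 mouse tissues, and in small intestine eosinophils sorted by a reporter of Nmur1. Each tissue had 3 or 4 libraries (24 in all), and the sorted cells had 5 positive and 6 negative libraries. Values were TPM, and the depth behind them is unknown. Genes with at least 1 TPM numbered 8818 ± 79.2 (SD, n = 4) per small intestine library and 7826 ± 53.2 (SD, n = 3) per lung library, the lowest mean among the 7 tissues. Sorted libraries had 7914 ± 12.1 (SD, n = 5) such genes when positive and 7812 ± 46.8 (SD, n = 6) when negative. Their table holds only 8001 genes, against 9844 for the tissues, so these counts cannot be compared with those of the tissue libraries.

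Nmur1 encodes a receptor of neuromedin U, the neuropeptide in the title of the series. The gene spans positions 86386303 to 86426228 of chromosome 1 on the minus strand (build mm10, ENSMUSG00000026237.5, protein coding). Its values in the 4 small intestine libraries were 47.39, 7.55, 24.4 and 26.05 TPM. It was listed at 0 in 19 of the 20 libraries of the other tissues, and spleen replicate 3 had 0.65 TPM. Exact two-sided permutation tests gave p = 0.0286 for small intestine against each of the 6 tissues, the smallest p these group sizes allow (0.0286 after Benjamini-Hochberg adjustment over 7 tests). In the sorted cells, which checks the labels, Nmur1 was 40.8 ± 13.2 TPM (SD, n = 5) in positive and 7.32 ± 5.03 TPM (SD, n = 6) in negative libraries. The change was 2.65 on the log2 scale (limma adjusted p = 0.0026, and 0.0012 with the replicate block), and 1 negative library was listed at 0. The exact permutation p was 0.00433, from 462 regroupings that did not keep same-numbered libraries apart.

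**Figure D1:**
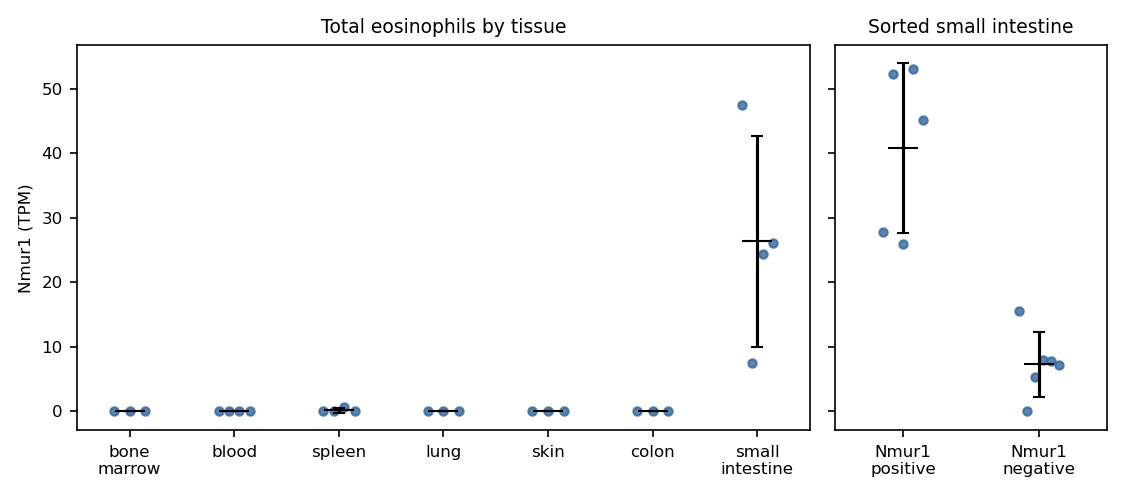
Nmur1 in TPM (vertical axis) by tissue (left) and by sort (right), 1 point per library, with bars for the mean and SD of each group. Small intestine libraries lie between 7.55 and 47.39 TPM while 19 of the 20 other tissue libraries are at 0, and the 2 panels come from separately normalised tables.

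The first comparison asked how eosinophils of the small intestine differ from those elsewhere. Against the mean of the 6 other tissues, small intestine eosinophils had higher levels of NF-kappaB pathway, sterol synthesis and aryl hydrocarbon receptor genes. Levels of granule protein genes were lower. Taken 1 tissue at a time, the NF-kappaB list missed the threshold against lung, skin and colon, and the granule list against blood and colon. The C-type lectin Clec4a4 averaged 487 ± 55.0 TPM (SD, n = 4) against 1.49 TPM in the other tissues, a log2 change of 8.01. Hcar2, a receptor for hydroxy-carboxylic acids, averaged 1055 ± 272 TPM against 21.2 TPM, and the chemokine Ccl4 averaged 8154 ± 384 TPM against 251 TPM. Among the genes that fell, Anxa1 was at 5 ± 2.71 TPM against 208 TPM, and Il1rl1, the receptor of interleukin 33, was at 0.470 ± 0.536 TPM against 48.9 TPM.

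In limma, 3999 of 9806 genes passed, 2422 higher and 1577 lower. The split depended on scaling, with 2010 higher and 1862 lower after median-ratio scaling and 1814 higher and 2140 lower after quantile normalization. The other largest rises were in Dpep2 (log2 change 7.07), the decoy interleukin 1 receptor Il1r2 (6.51), Gngt2 (6.43), Sirpb1a (6.21), Il1a (6.20), the thrombin receptor F2rl3 (5.99) and Adamdec1 (5.66). Among the other largest falls were Hist1h2ap (-5.21), Ear1 (-4.90), Prg3 (-4.68), Clec12a (-4.66), S100a6 (-4.63), Ear2 (-4.52) and Cd300ld3 (-4.37). All 4 small intestine libraries lay on the same side for each of these genes, as the rule for naming them required. Their limma adjusted p was at most 3.4e-07.

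Camera put 16 of 41 tested lists past the threshold, and 8 of them held with an estimated correlation. The genes of cholesterol and lipid synthesis rose together: 20 of 23 measured rose and 0 fell, also 20 and 0 when adjusted over the list alone (adjusted p = 1.18e-10, and 0.00214 with an estimated correlation). Insig1, a sterol sensor partner, averaged 124 ± 33.1 TPM against 6.90 TPM, and Idi1 and Msmo1, enzymes of sterol synthesis, averaged 128 ± 44.9 TPM against 7.25 TPM and 282 ± 66.0 TPM against 21.8 TPM. Of 8 genes of the aryl hydrocarbon receptor pathway, 7 rose and 0 fell (8 and 0 when adjusted over the list alone, adjusted p = 1.02e-06, and 0.00163 with an estimated correlation). These included Cyp1b1 at 51.3 ± 22.3 TPM against 0.321 TPM, the repressor Ahrr (log2 change 3.40), Tiparp (3.44) and the receptor gene Ahr (1.82).

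Of 32 genes of the NF-kappaB pathway 26 rose and 0 fell, with 27 and 1 when adjusted over the list alone (adjusted p = 3.07e-12, and 0.0231 with an estimated correlation). The list includes target cytokines such as Il1b, at 4774 ± 1035 TPM against 767 TPM, Ccl3 (log2 change 5.42) and Cxcl2 (5.29). Of 26 markers of activated intestinal eosinophils 19 rose and 1 fell, or 20 and 2 adjusted over the list alone (adjusted p = 1.18e-10, and 0.000595 with an estimated correlation), among them Itgax (4.77) and Tgm2 (4.48). Against the mean of lung, skin and colon alone, an alternative chosen after seeing the data, 11 NF-kappaB genes rose and 6 fell (camera adjusted p = 0.847), and 12 activation markers rose and 6 fell (0.123). Immediate early and dissociation response genes, which tissue processing can induce, had 28 of 37 members higher and 3 lower, or 29 and 3 adjusted over the list alone (adjusted p = 9.84e-07, and 0.136 with an estimated correlation). Against colon alone 1 of them was higher and 18 were lower (median -1.05, adjusted p = 1.91e-07, and 0.126 with an estimated correlation). Atf3 (5.21), Egr2 (4.78), Nr4a3 (4.24) and Egr1 (4.21) changed most against the mean of 6 tissues.

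Of 22 unfolded protein response genes 17 rose and 0 fell, with the same counts adjusted over the list alone (adjusted p = 5.13e-08, and 0.00783 with an estimated correlation), including the chaperone Hspa5 at 2070 ± 282 TPM against 469 TPM, Ddit3 (3.10) and Atf4 (1.92). Endosome and lysosome genes had 23 of 31 members higher and 2 lower, or 23 and 3 adjusted over the list alone (adjusted p = 1.27e-05, and 0.0476 with an estimated correlation), with Ctsl (3.69), Cd68 (3.64) and Laptm4a (2.77) in front, and 18 higher and 5 lower after quantile normalization. Of 25 cAMP and calcium response genes 16 rose and 1 fell, or 16 and 2 adjusted over the list alone (adjusted p = 0.000274, and 0.0476 with an estimated correlation), led by Rgs1 at 5042 ± 1471 TPM against 496 TPM. Against the mean of lung, skin and colon 14 of these rose and 3 fell (adjusted p = 0.0802, and 0.37 with an estimated correlation), and against colon alone 3 rose and 4 fell (0.749). The endosome and lysosome list had an adjusted p of 9.14e-05 against the mean of lung, skin and colon, and 0.0831 with an estimated correlation.

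Genes of eosinophil granule proteins fell, with 11 of 13 lower and 2 higher, also 11 and 2 adjusted over the list alone (adjusted p = 1.22e-05, and 0.0124 with an estimated correlation). Prg2, the major basic protein, was at 55.1 ± 20.2 TPM against 13460 TPM. The list did not pass against blood (7 lower and 2 higher, adjusted p = 0.1) or colon (2 lower and 1 higher, 0.127), and its call against skin (0.0215) was lost with an estimated correlation (adjusted p = 0.16). Prg2 was at 72330 ± 12110 TPM (SD, n = 3) in bone marrow alone. Against the mean of lung, skin and colon 6 granule genes fell and 1 rose (adjusted p = 0.000484, and 0.0522 with an estimated correlation), and Ear1 and Ear2 did not pass there (limma adjusted p = 0.12 and 0.22). Bone marrow libraries also carried transcripts of neutrophils and their precursors: S100a8 stood at 16460 ± 1382 TPM (SD, n = 3) there and at 15.3 ± 18.3 TPM in small intestine.

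The calls of 8 lists were lost with an estimated correlation. Ribosomal proteins had 60 of 82 genes lower and 4 higher (63 and 4 adjusted over the list alone, adjusted p = 6.07e-14, and 0.192 with an estimated correlation), such as Rps27a (log2 change -1.07) and Rpl37a (-0.98). At least 58 were lower against each of bone marrow, blood, spleen and lung, but the direction turned against skin, with 26 higher and 2 lower (adjusted p = 0.000856, and 0.564 with an estimated correlation), and against colon, with 6 higher and 0 lower (0.000119, and 0.474 with an estimated correlation). Oxidative phosphorylation had 16 of 44 genes lower and 6 higher (the same adjusted over the list alone, adjusted p = 0.000274, and 0.196 with an estimated correlation), such as Uqcrh (-1.18) and Ndufa4 (-0.99). After median-ratio scaling 25 were lower and 2 higher, and after quantile normalization 28 and 2. MHC class II presentation and costimulation had 8 of 13 genes higher and 1 lower (the same adjusted over the list alone, adjusted p = 0.00446, and 0.234 with an estimated correlation), with the checkpoint ligands Cd274 (4.12) and Pdcd1lg2 (4.11) and the costimulator Cd80 (3.3). Eicosanoid and leukotriene synthesis had 8 of 15 genes higher and 1 lower (the same adjusted over the list alone, adjusted p = 0.0184, and 0.234 with an estimated correlation), among them Ggt5 (3.07), Ptgs1 (2.18) and Pla2g7 (2.15). Chemokines had 9 of 16 genes higher and 3 lower, or 10 and 3 adjusted over the list alone (adjusted p = 0.0486, and 0.275 with an estimated correlation). Against the mean of lung, skin and colon the calls of MHC class II presentation (adjusted p = 0.0526), eicosanoid synthesis (0.0809), immediate early genes (0.688) and chemokines (0.78) were lost at the preset correlation too.

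Of 21 listed markers of B and plasma cells only 4 were measured. They were higher, with 3 called and 0 lower, the same adjusted over the list alone. The camera adjusted p was 0.0259, and 0.10 with an estimated correlation. From which cells this RNA came was not tested. Cd22, an inhibitory lectin of B cells, was at 75.8 ± 10.6 TPM against 0.888 TPM, whereas the plasma cell gene Jchain averaged 239 ± 446 TPM, mostly from small intestine replicate 3. Keratinocyte markers were lower in 2 of 3 (the same adjusted over the list alone, adjusted p = 0.0486, and 0.235 with an estimated correlation), with Perp at 3.40 ± 1.99 TPM against 46.3 TPM. Gut epithelium markers had 2 of 7 genes higher and 1 lower (adjusted p = 0.464), with Olfm4, a gene of crypt cells and granulocytes, at 116 ± 48.4 TPM against 9.22 TPM. Markers of stroma, endothelium and glia had 3 of 5 higher and 0 lower (adjusted p = 0.193), with the matrix gene Dcn at 30.4 ± 22.9 TPM against 3.98 TPM. Macrophage and monocyte markers had 7 of 13 higher and 2 lower (adjusted p = 0.259), with Cd68 higher and Ly6c2 lower (-3.83).

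The other lists did not pass. Higher and lower calls numbered 16 and 6 of 31 cytokine receptors, 9 and 2 of 19 genes of lipid uptake, storage and efflux, 5 and 1 of 10 neuropeptide and neurotransmitter receptors (Nmur1 and Ramp1 among the higher), 8 and 2 of 21 genes of MHC class I presentation, 8 and 5 of 18 extracellular matrix remodelling genes and 7 and 12 of 24 adhesion and integrin genes. They numbered 8 and 9 of 38 cell cycle genes, 12 and 6 of 29 genes of innate sensing, 12 and 9 of 30 genes of apoptosis and survival, 4 and 6 of 13 chemokine and chemoattractant receptors, 9 and 2 of 29 type I interferon response genes and 12 and 8 of 34 hypoxia and glycolysis genes. After quantile normalization the hypoxia and glycolysis counts were 10 and 13. In 3 lists the median and mean change differed in sign. Cytokines and growth factors had 10 and 6 of 24 called (median -0.10, mean 0.29), or 8 and 8 after median-ratio scaling and 7 and 9 after quantile normalization. Eosinophil identity genes had 11 and 8 of 25 (0.18 and -0.21), or 9 and 10 and then 7 and 10 under these scalings. Targets of interleukins 4 and 13 had 3 and 1 of 8 (-0.30 and 0.42). Among markers of other cells, higher and lower calls were 3 and 8 of 17 for granulocyte progenitors, 8 and 7 of 21 for neutrophils, 1 and 4 of 8 for mast cells and basophils, 2 and 4 of 15 for erythroid cells and platelets, 1 and 2 of 8 for dendritic cells, 2 and 3 of 7 for group 2 innate lymphoid cells, 1 and 1 of 3 for natural killer and cytotoxic cells, 0 and 2 of 2 for lung epithelium and 0 and 0 of 1 for T cells.

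**Figure D2:**
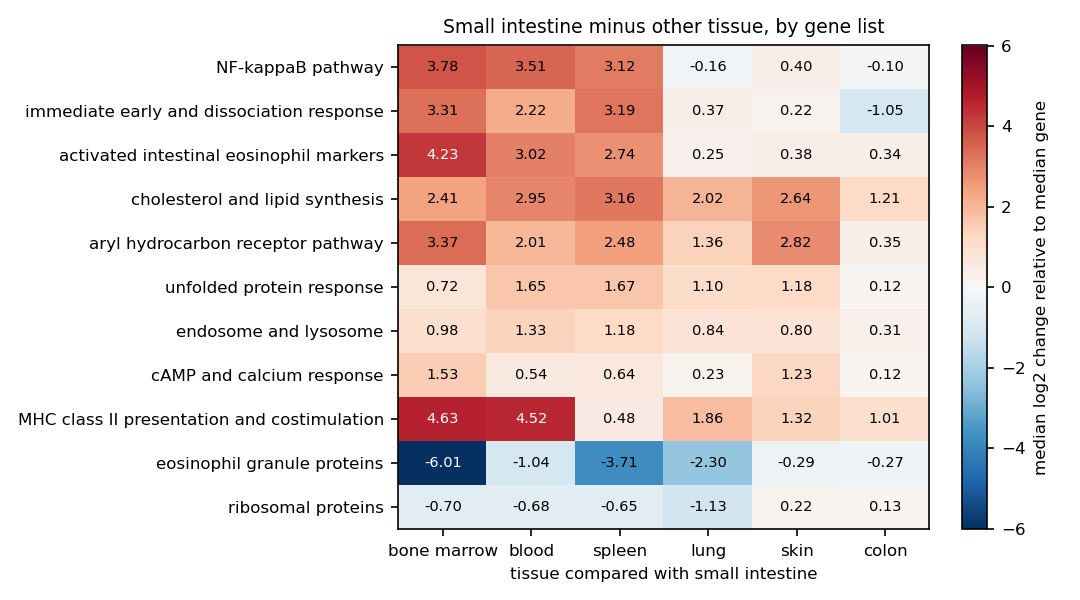
Median log2 change of 11 gene lists (rows), small intestine minus each other tissue (columns), relative to the median gene of that comparison, with red for higher and blue for lower in small intestine. NF-kappaB genes are at 3.78 against bone marrow and at -0.10 against colon, while sterol genes are at 1.21 or more in all 6 columns.

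The pairwise comparisons asked from which tissue the small intestine differs. Taken 1 tissue at a time, the cholesterol, aryl hydrocarbon receptor, and endosome and lysosome lists passed camera against all 6, and only the cholesterol list did so with an estimated correlation. That setting ended the call of the aryl hydrocarbon receptor list against colon (adjusted p = 0.0697 with an estimated correlation) and those of the endosome and lysosome list against all 6 (0.0541 to 0.158). The unfolded protein response passed against all but colon (adjusted p = 0.516), the cAMP and calcium response against all but lung (0.638) and colon (0.749), and activation markers against all but lung (0.673) and colon (0.149). Of these calls, those lost with an estimated correlation were the unfolded protein response against bone marrow (adjusted p = 0.0889), the cAMP and calcium response against blood (0.151) and skin (0.0866), and activation markers against skin (0.0866). NF-kappaB genes missed the threshold against lung (0.656), skin (0.112) and colon (0.709). Against bone marrow 4126 genes passed (2157 higher, 1969 lower). The split was 1821 and 2401 after median-ratio scaling and 2108 and 2271 after quantile normalization. Ccl4, Il1b, Cxcl2, Hcar2 and Ccl3 rose most, and Ear1, Ear2, the neutrophil granule genes Camp and Elane, and S100a8 fell most. Ear1 was at 11.1 ± 9.36 TPM in small intestine and at 26490 ± 4809 TPM in bone marrow. Against blood 4310 genes passed (2549 higher, 1761 lower, and 1986 higher and 2393 lower after quantile normalization). Il1r2, Il1b, Ccl4, Il1a and Cxcl3 rose most, from levels of 12.6 TPM or less. Hbb-bt, Hba-a1, Anxa1 and Hist1h2ap fell most together with Ctla2a, which was listed at 0 in all 4 small intestine libraries. Haemoglobin genes made up 7.96 ± 3.65% of TPM in blood (SD, n = 4), and without small intestine replicate 2 the adjusted p in limma was 0.19 for Hba-a1 and 0.085 for Hbb-bt. The call of Hba-a1 was also lost with only these tissues in the fit (0.054), with robust eBayes (0.078) and without blood replicate 1 (0.06) or 4 (0.061). Against spleen 4147 genes passed (2134 higher, 2013 lower). The split was 1920 and 2315 after quantile normalization and 1750 and 2380 with ribosomal protein genes left out. Ccl4, Cxcl2, Il1a, Il1r2 and Cxcl3 rose most, and Ear1, Ear2, Prg2, Hist1h2ap and Ngp fell most.

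Against lung 4918 genes passed, 3839 higher and 1079 lower, and the split was 2498 and 1894 after median-ratio scaling and 1874 and 2034 after quantile normalization. Lung libraries also had the fewest genes at 1 TPM or more. Gngt2, Lyz2, Abi3 and Dpep2 rose most together with Clec4a4, which was listed at 0 in all 3 lung libraries. The cytokine gene Osm, at 10.6 ± 7.17 TPM against 697 ± 20.9 TPM, Ear1, Map3k6, Ear2 and Slpi fell most. Against skin 3161 genes passed (1570 higher, 1591 lower, and 1679 higher and 1408 lower after median-ratio scaling). Adamdec1, Gngt2, Acp5, Hcar2 and Dpep2 rose most, and Retnla, at 19.7 ± 27.6 TPM against 2679 ± 344 TPM, Il1rl1, the serotonin transporter Slc6a4 and Ccl9 fell most, with Ccl8 listed at 0 in all 4 small intestine libraries. Colon was closest, with 1248 genes (552 higher, 696 lower). Clec4a4, Dpep2, Sirpb1a, the cadherin Cdh17 and Cd22 rose most, and Retnla, Lmna, Osm, Il1rl1 and Mptx1 fell most. Lmna was at 8.88 ± 1.01 TPM against 428 ± 169 TPM.

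Small intestine eosinophils stood apart from every other tissue in 338 genes, 214 higher and 124 lower. Median-ratio scaling gave 192 and 155, and quantile normalization 180 and 178. The smallest of the 6 log2 changes was 6.89 for Dpep2, 6.56 for Clec4a4, 5.65 for Sirpb1a, 5.50 for Cdh17 and 5.24 for F2rl3, and Clec12a (-3.68), S100a6 (-3.32), Emp3 (-3.28) and Hist1h2ap (-2.93) were among the largest falls. The call of Hist1h2ap (limma adjusted p = 0.018) was lost with robust eBayes (0.083), without small intestine replicate 2 (0.10) or 4 (0.094) and without colon replicate 2 (0.073) or 4 (0.091). The 6 comparisons share the small intestine libraries: 20 simulations of unchanged groups gave 0 genes, and independent lists of the observed sizes would share 0.431 higher and 0.092 lower genes, against 288 and 201 called in all 6. The first value leaves out real differences and the second the shared libraries, so neither is the number to expect where tissues differ. With the small intestine libraries split into groups of 2 and 3 tissues compared with each, chosen after seeing the data, 60 assignments called a median of 205 higher (189 to 239) and 133 lower (112 to 158) genes in all 6, and comparisons within a group still shared libraries.

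The second comparison asked how small intestine eosinophils with and without the Nmur1 reporter differ. Positive cells had higher levels of Nmur1 and lower levels of NF-kappaB pathway and ribosomal protein genes. These list calls held with an estimated correlation, but not with the replicate block as well (camera adjusted p = 0.111 for both). Rcan1, a calcineurin regulator, was at 123 ± 34.7 TPM (SD, n = 5) in positive and 13.2 ± 7.63 TPM (SD, n = 6) in negative libraries. Nfkbia, the inhibitor that NF-kappaB induces, was at 551 ± 151 TPM and 4505 ± 1376 TPM, and the transcription factor gene Myc was at 4.37 ± 2.35 TPM and 65.7 ± 14.5 TPM.

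In limma, 1152 of 7982 genes passed, 733 higher and 419 lower in positive cells. After median-ratio scaling 362 were higher and 592 lower, and after quantile normalization 428 and 529. The sorted table held no gene at 0 in all 6 negative libraries, so genes found only in positive libraries could not be counted. Besides Rcan1 (log2 change 3.02) and Nmur1, the largest rises were in Defa17 (3.21), Esam (2.73), Klra17 (2.6), the cytokine gene Il27 (2.41), Lyz1 (2.38), Jaml (2.35), Nr4a2 (2.30) and Cdh17 (2.16). Defa17 and Lyz1 are Paneth cell genes, and in positive replicate 1 they stood at 681 and 349 TPM. The call of Defa17 was lost with robust eBayes (adjusted p = 0.11), without that library (0.067) and without negative replicate 5 (0.053). That of Lyz1 was lost with the replicate number as a block (0.055, and 0.11 with median-ratio scaling as well). The largest falls were in Traf1 (-3.98), Myc (-3.95), Cst7 (-3.70), Cxcl10 (-3.70), Slpi (-3.69), Dusp2 (-3.52), the complement receptor C5ar1 (-3.44), Slc2a6 (-3.26), Nfkbia (-3.24) and Clec4a2 (-2.99).

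Of 36 lists tested 14 passed, and 2 of them held with an estimated correlation. Ribosomal proteins were lower in 78 of 82 genes and higher in 0, or 80 and 0 adjusted over the list alone (adjusted p = 7.28e-79, and 0.0301 with an estimated correlation). With the replicate block as well as an estimated correlation the adjusted p was 0.111. Rps19 was at 391 ± 38.4 TPM against 1242 ± 166 TPM, and Rps2 (-1.54) and Rpl13 (-1.47) followed. Ribosomal protein genes made up 8.34 ± 0.553% of TPM in positive and 13.5 ± 1.37% in negative libraries. The NF-kappaB pathway was lower in 16 of 31 genes and higher in 5, or 18 and 5 adjusted over the list alone (adjusted p = 2.99e-12, and 0.000921 with an estimated correlation, or 0.111 with the block as well). After median-ratio scaling 18 were lower and 2 higher. Tnf (-2.66) and Sod2 (-2.46) were among the lower genes. Ccl4 (0.70), Ccl3 (0.52) and Il1b (0.25) were among the higher genes, and Cxcl2 (-0.61) was not called. Of 9 measured markers of macrophages and monocytes 6 were higher in positive cells, as given below. The 2 dendritic cell markers measured, of 19 listed, were lower.

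The other 12 calls were lost with an estimated correlation. Oxidative phosphorylation had 7 of 44 genes lower in positive cells and 0 higher, the same adjusted over the list alone (adjusted p = 8.3e-08, and 0.215 with an estimated correlation), such as Atp5e (-0.96) and Ndufa6 (-0.81). After median-ratio scaling 17 were lower, and after quantile normalization 9. MHC class I presentation had 7 of 20 lower and 0 higher, or 9 and 1 adjusted over the list alone (adjusted p = 6.23e-07, and 0.0677 with an estimated correlation), such as H2-Q6 (-2.88) and H2-K1 (-1.19). Cytokines and growth factors had 8 of 19 lower and 2 higher (the same adjusted over the list alone, adjusted p = 1.79e-05, and 0.144 with an estimated correlation), with Il6 (-2.94) and Il23a (-2.89) lower and Il27 higher. Granule proteins had 3 of 6 lower and 0 higher (the same adjusted over the list alone, adjusted p = 3e-05, and 0.0677 with an estimated correlation), namely Cst7, Prg2 (-2.13) and Ctsz (-1.30). Innate sensing had 7 of 24 lower and 2 higher, or 7 and 3 adjusted over the list alone (adjusted p = 0.000379, and 0.0782 with an estimated correlation), with Clec12a (-2.76) and Casp4 (-2.51). Apoptosis and survival had 6 of 26 lower and 2 higher, or 6 and 3 adjusted over the list alone (adjusted p = 0.0372, and 0.131 with an estimated correlation), with Fas (-2.57) and Bax (-0.90), and with 6 lower and 0 higher after median-ratio scaling. Chemokines had 4 of 11 lower and 3 higher, or 6 and 3 adjusted over the list alone (adjusted p = 0.0372, and 0.144 with an estimated correlation), with Cxcl1 (-2.13) and Ccl9 (-2.05).

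Cholesterol and lipid synthesis had 14 of 23 genes higher in positive cells and 0 lower, or 19 and 0 adjusted over the list alone (adjusted p = 1.3e-07, and 0.144 with an estimated correlation), with Fdft1 (1.43), Sqle (1.33) and Msmo1 (1.16). The cAMP and calcium response had 8 of 24 higher and 0 lower, or 11 and 0 adjusted over the list alone (adjusted p = 0.00248, and 0.221 with an estimated correlation), with Rcan1, Nr4a2, Rgs1 (1.5) and Nr4a1 (0.87). The call of Nr4a1 was lost with robust eBayes (adjusted p = 0.065) and without positive replicate 8 (0.061). Endosome and lysosome genes had 7 of 31 higher and 1 lower, or 11 and 1 adjusted over the list alone (adjusted p = 0.0261, and 0.50 with an estimated correlation), with Ctsl (1.07) and Laptm4a (0.79) higher. After median-ratio scaling 3 were higher and 1 lower. Cell cycle genes had 2 of 14 higher and 0 lower, or 7 and 0 adjusted over the list alone (adjusted p = 0.0393, and 0.144 with an estimated correlation), namely Mcm6 (1.52) and Mcm7 (1.5). Macrophage and monocyte markers, 9 measured of 26 listed, had 6 higher and 0 lower, or 7 and 0 adjusted over the list alone. The camera adjusted p was 0.00108, and 0.144 with an estimated correlation. Lyz2 was at 281 ± 69.0 TPM against 67.0 ± 27.1 TPM, and Cd68 (0.99) was also higher. After quantile normalization 4 were higher, and the calls of Apoe and Ace were lost (limma adjusted p = 0.052 and 0.11). Of the called markers, Nr4a1 is also on the cAMP and calcium response list and Cd68 on the endosome and lysosome list. With the replicate block the hypoxia and glycolysis list also passed (adjusted p = 0.044, against 0.0588 without the block), a call lost with an estimated correlation (adjusted p = 0.419). Among lists that did not pass, 9 of 37 immediate early genes were higher and 6 lower (adjusted p = 0.759, median 0.19, mean -0.06), with Egr2 (2.12) higher and Ier3 (-2.94) lower, and 7 of 25 activation markers were higher and 3 lower (adjusted p = 0.743), with Cd86 (1.19) higher and Cd69 (-1.59) lower.

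**Figure D3:**
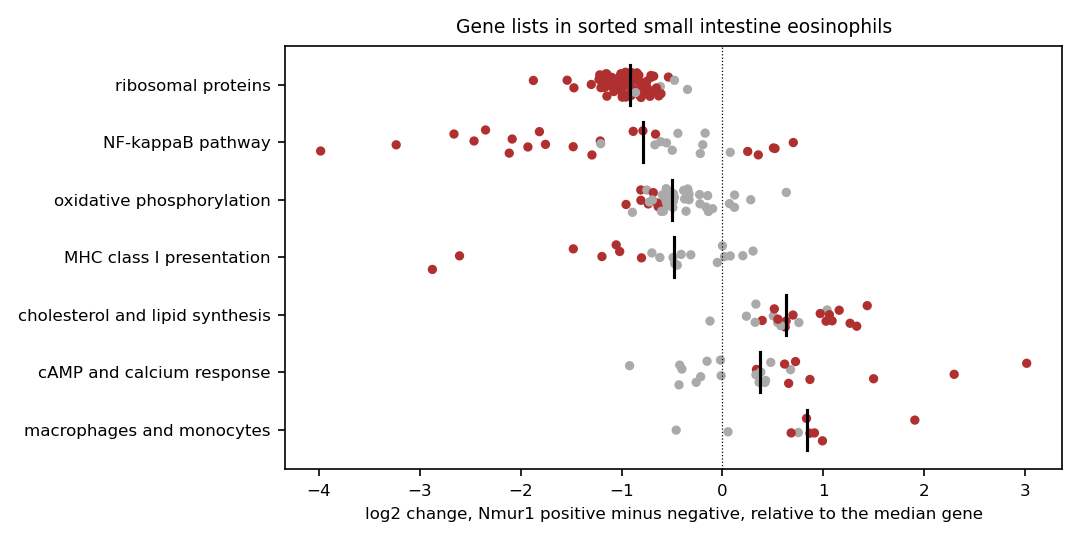
Log2 change of each gene (horizontal axis, positive minus negative libraries, relative to the median gene) in 7 gene lists (rows), in red where the gene passed the test and grey where it did not, with a black bar at the list median. The median is -0.91 for ribosomal proteins, -0.79 for the NF-kappaB pathway and 0.63 for cholesterol and lipid synthesis.

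Genes that set the small intestine apart from every other tissue were then followed in the sorted cells, which are other libraries. Of the 214 higher genes 206 were measured, among them Nmur1, whose reporter defined the sort. In positive cells 119 of the 206 were higher and 2 lower, against 733 and 419 of all 7982 genes tested. The median log2 change of the 206 was 0.52 (camera p = 2.82e-26, and 0.00482 with an estimated correlation). After median-ratio scaling 95 were higher and 4 lower. Of the 124 lower genes 105 were measured, with 45 lower and 1 higher in positive cells and a median of -0.78 (camera p = 3.69e-25, and 0.000626 with an estimated correlation). Cdh17, for example, was in the first set and rose in positive cells, and Clec12a was in the second and fell.

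**Figure D4:**
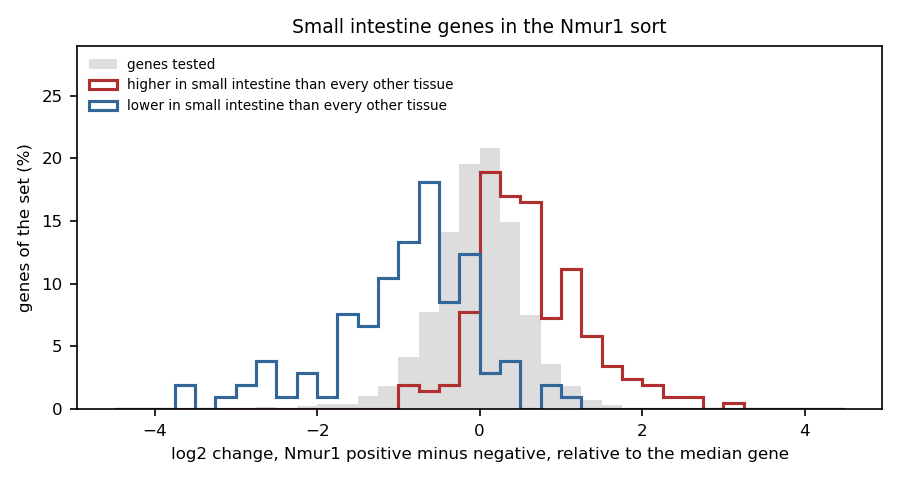
Share of genes in percent (vertical axis) by log2 change, positive minus negative libraries, relative to the median gene (horizontal axis), for the genes tested (grey) and for genes higher (red) or lower (blue) in small intestine than in every other tissue. The medians are 0.52 for the red and -0.78 for the blue set.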

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

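All tests of explanations and of other groupings in this part were chosen after the results were seen. In groups of 4 to 6 libraries, Dixon's test marks a library that lies far from the others, and chance alone marks about 1 in 20 groups. It marked 46 of 402 groups of libraries for library measures and the genes named in the text, many of them groups near 0.

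Ribosomal protein genes were lower in Nmur1 positive libraries. After median-ratio scaling with the replicate block 80 of 82 genes were still called lower. Median-ratio scaling lowered the median change of all genes from 0.216 to 0.045. It therefore favours lower calls, and this count cannot test TPM scaling as a cause. A single factor per library moves genes nearly alike. It does not account for the list median of -0.91 relative to the median gene in the main fit. Transcript length and GC content as the whole cause are argued against by other genes matched on length, level and GC content. In the blocked fit with median-ratio scaling their medians averaged -0.27 (range -0.56 to -0.03 in 10000 draws), against -0.98 for the ribosomal protein genes. A difference between the sorted cells stays open and was not tested apart from these. The share of ribosomal protein genes was highest in negative replicate 5, at 16.15% of TPM against 12.37% to 13.66% in the other negative libraries.

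NF-kappaB pathway genes were lower in Nmur1 positive libraries. After median-ratio scaling with the replicate block 20 of 31 genes were called lower and 2 higher. That scaling favours lower calls here too, so this count cannot test TPM scaling as a cause. A single factor per library does not account for the list median of -0.79 relative to the median gene in the main fit. RNA of other cell types in the negative sort stays open. Of 44 markers of other cells 5 were lower and 15 higher in positive libraries, or 8 and 12 after median-ratio scaling with the replicate block. Bst2 (log2 change -0.93) and Cst3 (-0.82), the 2 dendritic cell markers measured of 19 listed, were both lower. Bst2 is also on the type I interferon list, and Cst3 was also lower in small intestine than in every other tissue. They can therefore not tell dendritic cell RNA from a difference between eosinophils. The criterion for this test was made more cautious after those markers had been seen. A difference between the sorted cells also stays open.

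Several gene lists were higher in small intestine than in the mean of 6 tissues, and a difference shared by lung, skin, colon and small intestine is a candidate explanation. Against the mean of lung, skin and colon, NF-kappaB genes had a median change of 0.24. Immediate early and dissociation response genes had -0.04, and neither list passed camera there. That mean can cancel opposite differences, so it cannot decide the question alone. Against lung, skin and colon singly the NF-kappaB medians were -0.16, 0.4 and -0.1. None passed, and the explanation stays open for that list. The immediate early medians were 0.37, 0.22 and -1.05. Against colon 1 of these genes was higher and 18 were lower (adjusted p = 1.91e-07, and 0.126 with an estimated correlation). A level shared with colon was therefore not shown for them. A difference shared by all 4 is argued against for cholesterol and lipid synthesis (2.01), the aryl hydrocarbon receptor pathway (1.53) and the unfolded protein response (0.81), which passed. One shared by colon and small intestine is argued against for cholesterol and lipid synthesis (1.21 against colon, adjusted p = 1.55e-08, and 0.0142 with an estimated correlation), but stays open for the unfolded protein response (0.12, 0.516) and the aryl hydrocarbon receptor pathway (0.35, 0.0134, and 0.0697 with an estimated correlation). How these cells were isolated cannot be separated from the tissues they came from.

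For each comparison the libraries were regrouped into groups of the same sizes, and among the groupings tried only the real one gave as many genes. With 35 splits, 1 in 35 is the smallest share possible. Where 100 splits were used, they were the real grouping and a random draw of others. Chance is thus made less likely for these counts but not excluded. Of 35 splits each, the real count and the highest other were 4126 and 2620 for bone marrow, 4310 and 2 for blood, 4147 and 14 for spleen, 4918 and 2948 for lung, 3161 and 1659 for skin, and 1248 and 653 for colon. Of 100 splits each they were 3999 and 632 for the mean of 6 tissues, 338 and 0 for every other tissue, and 1152 and 2 for the Nmur1 sort. Among 48 splits of the sorted libraries that part the 4 pairs, the highest other count was 520, above the 2 of the random draw.

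In blood the library apart from the others was replicate 1 for Clec4a4 (0.49 TPM), Dmkn (0.61) and Dpep2 (0.21), replicate 2 for Ahrr (1.25), Gngt2 (9.72) and Sirpb1a (4.83), and replicate 3 for Cdh17 (1.63) and Olfm4 (1.79). Blood replicate 4 was the highest for Jchain (2.55 TPM), Mptx1 (1.36) and Ramp1 (6.06), and the lowest for Cxcl2 (10.82) and Egr1 (1.55). In spleen, replicate 1 was the highest for Clec4a4 (0.5 TPM), Ly6c2 (770.4), Ndufa4 (712.4), Olfm4 (13.73) and Osm (20.64). Spleen replicate 2 was the highest for Cdh17 (0.27 TPM) and the lowest for Hba-a1 (1.61) and Hbb-bt (3.24), whose other values were at least 2596 and 1517 TPM. Spleen replicate 3 was the highest for Cd68 (15.58 TPM), Il1b (19.82), Nmur1 (0.65) and Pdcd1lg2 (0.45), and replicate 4 for Elane (86.86) and Sqle (5.28).

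In small intestine, Cd300ld3 was at 0.75 TPM in replicate 1 and at 0 in the others, Il1b was lowest in replicate 2 (3236 TPM) and Clec4a4 was lowest in replicate 3 (404.9 TPM). Replicate 4 was the lowest for Ear2 (0 TPM) and Perp (0.49) and the highest for Mptx1 (0.82) and Slc6a4 (0.99). Among positive libraries, replicate 1 was the highest for Defa17 (681 TPM) and the lowest for Msmo1 (220.2), and replicate 4 was the lowest for Rps2 (157.3). Among negative libraries, replicate 7 was the lowest for C5ar1 (10.79 TPM), Slc2a6 (38.15) and Traf1 (20.67), and replicate 3 had 0 TPM for both Il27 and Nmur1. Negative replicate 2 was the highest for Cd22 (53.78 TPM), replicate 4 for Il6 (50.28) and replicate 5 for Ndufa6 (594.4).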

How the results depend on the processing

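Every total of changed genes, higher and lower together, stayed within 1.5 times its reported value under the alternatives run, except where a change of at least 2-fold was required, which by its construction keeps fewer genes (2119 for the mean of 6 tissues and 526 for the Nmur1 sort). Higher and lower genes counted apart moved more with scaling, as for lung and the sort. With an estimated correlation 8 of 16 lists kept their call in the tissues and 2 of 14 in the sort. Nmur1 kept its direction and call throughout. Chosen after seeing the data were lung, skin and colon as the other side, haemoglobin genes left out, and the block with median-ratio scaling. Against lung, skin and colon, 3295 genes passed and 7 named genes changed sign: Cxcl10 (-0.01), H2-Q6 (-0.25), Hdc (-0.23), Nkg7 (0.08), Prtn3 (0.36), Ptgs2 (-0.84) and Slc2a6 (-0.32); only Ptgs2 passed there (limma adjusted p = 0.034). In the sort, Hdc was at -0.15 with the block and median-ratio scaling, and Napsa at 0.05 with the replicate block and between -0.15 and 0.02 with a positive library left out. The cause of these sign changes was not tested. Neither Hdc nor Napsa had passed in the sort.

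With the replicate block 1342 genes passed in the sort. Among named genes the block ended the calls of Csf3r, Il13ra1, Lgals1, Lyz1, Mrgpra2a, Ndufb10, Stat2, Txk and Xbp1, and among lists it made that of hypoxia and glycolysis, lost with an estimated correlation (0.419); it changed no other call at the preset correlation. Tissue replicate numbers share only a number: deviations of same-numbered libraries correlated by a median of 0.0013 (range -0.05 to 0.09, 62 pairs), and the block gave 3965 genes for the mean of 6 tissues and 317 for every other tissue. With each library left out in turn, counts ranged from 3418 to 4072 for the mean of 6 tissues, 274 to 358 for every other tissue, 3438 to 3905 for bone marrow, 3907 to 4041 for blood, 3736 to 3927 for spleen, 4341 to 4645 for lung, 2742 to 2911 for skin, 959 to 1178 for colon and 867 to 1161 for the sort. In these runs the log2 change of Nmur1 ranged from 4.14 to 4.98 in the tissues and from 2.11 to 2.92 in the sort. In them 14 to 16 and 11 to 17 lists passed. Pseudocounts of 0.1 and 5 moved the Nmur1 change more, to 7.66 and 2.47 in the tissues and to 3.3 and 1.96 in the sort. Of 3525 values of 147 named genes against the mean of 6 tissues 15 lost their call with a library left out, and of 1331 values of 121 named genes in the sort 81 did. Depth is unknown, so values near 0 cannot be told from undetected transcripts.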

Other observations

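Receptor and adhesion genes outside the lists that passed also differed between Nmur1 positive and negative eosinophils. The complement receptor C3ar1 was at 3.93 ± 2.37 TPM (SD, n = 5) in positive and 12.3 ± 2.19 TPM (SD, n = 6) in negative libraries, and the chemokine receptor Cxcr2 was at 29.1 ± 12.8 TPM against 6.45 ± 2.87 TPM. The integrin gene Itgb7 (log2 change -2.07) was lower. Ramp1, a subunit of the receptor of the neuropeptide CGRP, was at 22.7 ± 4.26 TPM against 8.65 ± 3.33 TPM, a call lost only with the block and median-ratio scaling together (limma adjusted p = 0.066). Mrgpra2a (1.66) was higher, and its call was lost with quantile normalization, with the block, with the block and median-ratio scaling, and without positive replicate 5 or 8 (limma adjusted p from 0.057 to 0.11). Of 14 genes of eicosanoid synthesis, Hpgds (1.52), Ptgs1 (1.29) and Ggt5 (1.14) were higher in positive libraries, and Ptgs2 (-1.31), Alox5ap (-0.90) and Alox15 (-0.64) were lower. The call of Ptgs2 was lost without negative replicate 7 or 8 or positive replicate 3 or 4 (limma adjusted p from 0.058 to 0.076). Alox5ap and Alox15 were named after their values were seen and were not run under the alternatives. Cd22 (1.68) and Il1r2 (0.81), which were higher in small intestine than in the mean of 6 tissues, were also higher in positive libraries.

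The lists these genes belong to, and the others counted here, did not pass in the sort without the replicate block. Higher and lower calls numbered 3 and 0 of 7 neuropeptide and neurotransmitter receptors, 2 and 3 of 11 chemokine and chemoattractant receptors, 4 and 6 of 22 adhesion and integrin genes, 3 and 3 of 14 eicosanoid genes, 6 and 3 of 24 cytokine receptors, 2 and 0 of 11 genes of MHC class II presentation and 4 and 1 of 8 aryl hydrocarbon receptor genes. They numbered 4 and 3 of 23 eosinophil identity genes, or 1 and 4 after median-ratio scaling and 5 and 2 after quantile normalization. For lipid uptake, storage and efflux they were 2 and 1 of 16, or 1 and 2 after median-ratio scaling. Hypoxia and glycolysis had 4 and 6 of 31, the type I interferon response 2 and 3 of 25, and matrix remodelling 2 and 4 of 18. Calls were 2 and 1 of 21 for the unfolded protein response and 2 and 1 of 5 for targets of interleukins 4 and 13. Among markers of other cells they were 3 and 1 of 11 for neutrophils, 0 and 0 of 7 for granulocyte progenitors, 0 and 1 of 4 for mast cells and basophils, 1 and 0 of 3 each for B and plasma cells, group 2 innate lymphoid cells, and erythroid cells and platelets. Too small to test were gut epithelium (1 and 0 of 2), keratinocytes (0 and 0 of 1), lung epithelium (0 and 0 of 1), T cells (0 and 0 of 1), natural killer cells (1 and 1 of 2), dendritic cells (0 and 2 of 2) and stroma (1 and 0 of 2).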
